A study of Homo sapiens with 12 samples.

How the data were processed

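Total RNA of HMLER cells sorted by flow cytometry was reverse transcribed with an oligo(dT) primer, transcribed into biotin-labelled RNA and hybridized to Affymetrix GeneChip arrays, per the labels' protocols. The deposited log2 values of 54675 probe sets on 12 arrays were used as given. The scale was read from the values, and how the authors corrected background, normalized and summarized the probes is not given in the sources used here. The authors' deposited tables hold an adjusted p-value, a fold (ratio) and its reciprocal for each row, with gene symbols. The arrays, test and threshold behind the deposited p-value and ratio columns are not given in the sources used here. The deposited tables give gene symbols without probe set IDs, so their rows were not joined to the log2 values.

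Arrays were assigned to GD2+, GD2-, CD44high and CD24high by their titles and sorted-population labels, 3 arrays each. Short description codes on the GD2 arrays could be read the other way round, and the text therefore speaks of labelled arrays. Control probe sets (62) were left out of all tests. Linear models were fitted to the 54613 other probe sets with limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups over all 12 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment (threshold 0.05). The comparisons between populations and the difference between the sorts came from this fit. Counts at the highest adjusted p and smallest fold of the deposited tables came from a limma fit of the 6 arrays of a sort alone, with the fit of 12 arrays as an alternative chosen after the data were seen. Correlations of log2 fold changes are across probe sets or genes. The analysis had been planned by gene, with 1 probe set per gene and the camera test of gene lists. These steps were not run, because the tables used here do not pair probe sets with genes. Array results are therefore by probe set, with 2 per direction, those with the largest change among probe sets past the threshold. Within a sort, the 3 arrays of a group had also all to lie beyond the 3 of the other, which chance gives in 10% of cases. Adjusted p-values on the arrays are from limma. Same-numbered arrays of GD2- and CD24high deviated from their group means together, if weakly (r = 0.14, 0.10 and 0.13 across probe sets), which comes from the data and not from the labels. A fit with the replicate number as a block gave 21300 probe sets for that comparison, within 1.5 times the count without it.

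Symbols of the deposited tables were matched to a table of human gene symbols and synonyms (GRCh38.p14). Of the symbols in the GD2 table, 393 were current, 40 older and 9 not matched, and these numbers were 336, 37 and 12 for the CD44/CD24 table. Unmatched symbols were kept as given. Rows without a symbol (32 and 36) and with a symbol turned into a date (2 and 3) were left out. This gave 442 and 384 genes, of which 3 in the GD2 table, AP1S2, EPB41L5 and QSOX1, had rows in both directions and were left out of direction counts. The log2 fold changes of a gene's rows were averaged. The 21 gene lists and the rule for named genes were fixed before the data were examined: the 10 largest changes in each direction per comparison, CD44, CD24, ST8SIA1 and B4GALNT1, and up to 4 members per list with the smallest adjusted p. The rule was applied to the deposited tables, where the overlap of single arrays could not be tested. For each list, genes listed as higher and lower were compared with the other genes of the same table by two-sided Fisher's exact tests (scipy 1.17.1), adjusted over the lists with at least 1 gene in the table (statsmodels 0.14.6). This design was chosen after the data were seen, does not test enrichment against all genes measured, and treats genes as independent, which they are not.

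The limma step was tested on simulated data with 67, 67 and 66 probe sets changed by 0.5, 1 and 2 log2 units. For GD2+ against GD2-, 17.9%, 71.6% and 95.5% of these were recovered, with 4 false calls among 127. For CD44high against CD24high these shares were 14.9%, 71.6% and 95.5%, with 2 false calls among 123. In 500 random lists of 30 genes from the GD2 table, 5.0% passed an unadjusted threshold of 0.05.

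Alternatives included quantile normalization, median centring, leaving out the dimmest 40% of probe sets or those ending in _x_at or _s_at, a trended and robust variance, a fold of at least 2, a replicate block, only the 6 arrays compared and leaving out each array.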

Results

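RNA from HMLER cells, human mammary epithelial cells made tumorigenic with an activated Ras oncogene, was measured on 12 single-colour Affymetrix arrays. The cells had been separated by flow cytometry in a pair of sorts. In the GD2 sort, cells carrying the ganglioside GD2, a sialic acid-containing glycolipid of the plasma membrane, were labelled GD2+ and cells without it GD2-. In the CD44/CD24 sort, cells with much CD44, a hyaluronan receptor, and little CD24, a small glycoprotein of the epithelial surface, were labelled CD44high, and cells with the reverse profile CD24high. Each of the 4 populations was represented by 3 arrays, and the labels do not say whether these came from separate cultures, so p-values measure only the spread between these arrays. The data comprised log2 values of 54675 probe sets, of which 62 were control probe sets and 54613 were tested. The authors' deposited table for GD2+ and GD2- cells held 600 rows, and their deposited table for CD44high and CD24high cells held 578 rows. Genes are named here from these deposited tables. The arrays are described by probe set, since the files used here do not pair probe sets with genes.

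Array medians were alike, between 5.423 and 5.469 log2 units. Replicate arrays of a population correlated with r between 0.9738 and 0.9966 across probe sets, which are not independent replicates, and no pair of arrays was identical. The median SD between replicate arrays was 0.141 log2 units in arrays labelled GD2+, 0.173 in GD2-, 0.127 in CD44high and 0.145 in CD24high (n = 3 each). The number of arrays limits the precision. In a principal component analysis, the leading component carried 58% of the variance and separated the 6 arrays of the GD2 sort from the 6 arrays of the CD44/CD24 sort. The next component carried 18.4% and placed the arrays labelled GD2+ and CD24high on one side and those labelled GD2- and CD44high on the other. GD2- replicate 3 lay farther out, at -78 against -18.4 and -12.2 for the other GD2- arrays, and correlated with them at r = 0.9738 and 0.9768.

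The direction of the fold changes in the authors' deposited tables had to be read from their content, because their headers do not name the numerator. CD24 was 67.4-fold apart in the authors' deposited CD44/CD24 table, and this side was taken as CD24high, the population sorted for CD24. The GD2 table has the same layout and was read the same way, so that its direction is likely rather than stated. On this reading ST8SIA1, which encodes GD3 synthase and makes the precursor of GD2, was 8.26-fold higher in GD2+ cells in the authors' deposited table (adjusted p = 0.000947). CD24 was 12.8-fold lower in GD2+ cells in the same authors' deposited table, across 4 rows. CD44 was listed as lower in GD2+ cells, by 2.88-fold in 1 row of the authors' deposited table. CD44 was also listed as lower in CD44high cells, by 4.22-fold across 2 rows of the authors' deposited table, opposite to the surface protein used in that sort. Which CD44 transcripts these rows measured is not given. B4GALNT1, the enzyme that makes GD2 from GD3, was listed in neither of the authors' deposited tables. As a list, the sort markers and GD2 enzymes did not differ in direction from the other genes of either authors' deposited table (adjusted p = 0.654 and 1, Fisher's exact test). All fold changes of a gene with several rows are geometric means over its rows.

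Which genes separate GD2+ from GD2- cells was addressed by the authors' deposited GD2 table. Matrix and mesenchymal genes led the genes listed as higher in GD2+ cells. GREM1, which encodes a secreted antagonist of bone morphogenetic proteins, was 1307-fold higher in the authors' deposited table (adjusted p at most 2.73e-06). The fibrillar collagen genes COL3A1, COL1A2 and COL1A1 were 1085-fold, 685-fold and 213-fold higher in the authors' deposited table. PRRX1 and ZEB1, transcription factors that drive the epithelial-mesenchymal transition (EMT), were 485-fold and 206-fold higher in the authors' deposited table. The other genes among the 10 with the largest folds on this side of the authors' deposited table were ABI3BP (460-fold), the basement membrane gene NID1 (345-fold), the pentraxin gene PTX3 (274.5-fold) and COL6A3 (175-fold). Genes listed as lower had smaller folds. The largest in the authors' deposited table were those of ANO1, a calcium-activated chloride channel gene (20.7-fold), SERPINB13 (19.8-fold), TINCR, listed as PLAC2 (17.3-fold), BLNK (14.4-fold) and EHF, an epithelial Ets factor gene (13.8-fold). HS3ST1 was 13.2-fold, PNLIPRP3 13.0-fold, ANKRD22 12.6-fold and TMEM30B 12.3-fold lower in the authors' deposited table. The largest log2 fold change of a row in the authors' deposited GD2 table was 10.5, above the largest of 5.81 and 7.30 within the labelled sorts on the arrays.

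By gene group, all 42 mesenchymal and matrix genes in the authors' deposited GD2 table were listed as higher in GD2+ cells (two-sided Fisher's exact test against 190 higher and 207 lower among the other genes, adjusted p = 5.71e-12 over 13 lists). Besides GREM1 and COL1A1, they included FBN1, 92.9-fold higher, and VCAN, 32.3-fold higher in the authors' deposited table. All 31 epithelial junction and identity genes in the authors' deposited table were listed as lower (adjusted p = 1.37e-10, Fisher's exact test). ESRP1, an epithelial splicing regulator gene, was 11.7-fold lower, ST14 8.94-fold, CDS1 5.14-fold and ESRP2 5.02-fold lower in the authors' deposited table. Of 9 basal and myoepithelial genes, 8 were listed as lower (adjusted p = 0.0414, Fisher's exact test; 0.116 with only rows of at least 4-fold). TRIM29 was 7.37-fold, COL17A1 5.82-fold and TP63 4.14-fold lower in the authors' deposited table, whereas MME, a surface peptidase gene, was 70.7-fold higher. Of the luminal genes, ERBB3 was 11.6-fold and KRT18 3.97-fold lower in the authors' deposited table (adjusted p = 0.412, Fisher's exact test).

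All 7 NF-kB and inflammatory cytokine genes in the authors' deposited GD2 table were listed as higher in GD2+ cells (adjusted p = 0.0414, Fisher's exact test; 0.072 with only rows of at least 4-fold). TNFAIP6 was 134.5-fold, the chemokine genes CXCL6 and CXCL1 35.8-fold and 26.6-fold, and C3 4.01-fold higher in the authors' deposited table. All 5 EMT transcription factor genes were listed as higher (adjusted p = 0.137, Fisher's exact test), with ZEB2 50.1-fold and TWIST1 10.3-fold higher in the authors' deposited table. Of 12 fibroblast marker genes, 11 were listed as higher (adjusted p = 0.0286, Fisher's exact test; 0.0686 with only rows of at least 4-fold), POSTN by 55.0-fold in the authors' deposited table. The exception, MFAP5, named after its value was seen, was 11.1-fold lower in the authors' deposited table. Of the 18 fibroblast markers, 15 also belong to the mesenchymal or EMT lists, so the counts overlap. Among TGF-beta and BMP pathway genes, 4 were listed as higher and FST as lower (adjusted p = 0.611, Fisher's exact test). LTBP1 was 38.3-fold and TGFBR3 4.70-fold higher in the authors' deposited table. Of the ganglioside enzyme genes, ST6GALNAC5 was 10.1-fold and FUT1 3.33-fold lower in the authors' deposited table, and ST8SIA1 was higher (adjusted p = 0.654, Fisher's exact test). FADS1 and FADS2, from the cholesterol synthesis list, were 5.79-fold and 3.16-fold higher in the authors' deposited table (adjusted p = 0.651, Fisher's exact test). The only squamous gene listed was SERPINB13 (adjusted p = 0.651, Fisher's exact test). The only leukocyte marker was SRGN, 18.4-fold higher in the authors' deposited table (adjusted p = 1, Fisher's exact test). Stem cell, cell cycle, interferon-stimulated, RAS-MAPK output, immediate early, hypoxia, unfolded protein response and endothelial marker genes had no member in the authors' deposited GD2 table.

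For CD44high against CD24high cells, the largest folds in the authors' deposited CD44/CD24 table were those of genes listed as lower in CD44high cells. EPCAM, an epithelial adhesion molecule gene, was 239-fold lower in the authors' deposited table (adjusted p = 0.00718). CDH1, which encodes E-cadherin, was 117-fold lower in the authors' deposited table, and ESRP1, listed as RBM35A, was 104-fold lower. FGFBP1 was 144-fold, SPRR1B 107-fold, KLK5 103-fold, S100A14 96.65-fold, KRT15 91.2-fold, KRT6B 90.5-fold and ZBED2 89.9-fold lower in the authors' deposited table. Genes listed as higher had smaller folds. VCAM1, a leukocyte adhesion molecule gene, was 39.4-fold higher in the authors' deposited table (adjusted p = 0.00256). LUM, a matrix proteoglycan gene, was 36.4-fold, TNFAIP6 22.8-fold, CCDC102B 22.6-fold and CYP1B1 20.2-fold higher in the authors' deposited table. ST8SIA1 was 15.0-fold, PNMA2 13.7-fold, POM121L9P 11.3-fold, SERPINF1 11.1-fold and NPR3 10.6-fold higher in the authors' deposited table. The largest negative log2 fold change of a row in the authors' deposited CD44/CD24 table was -7.9. No probe set fell as far on the arrays, where the lowest values were -3.09 for CD44high against CD24high and -4.22 for GD2+ against GD2-. The largest positive value in that table was 5.3, below the 7.30 on the arrays labelled CD44high and CD24high.

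By gene group, all 25 epithelial junction and identity genes in the authors' deposited CD44/CD24 table were listed as lower in CD44high cells (adjusted p = 0.00103 over 14 lists, Fisher's exact test). PKP3 was 10.2-fold and OVOL2 8.76-fold lower in the authors' deposited table. All 18 basal and myoepithelial genes were listed as lower (adjusted p = 0.00581, Fisher's exact test; 0.0714 with only rows of at least 4-fold). KRT6A was 56.1-fold, COL17A1 39.8-fold, TP63, a basal transcription factor gene, 36.7-fold and TRIM29 22.8-fold lower in the authors' deposited table. Of 9 mesenchymal and matrix genes, 8 were listed as higher (adjusted p = 0.00381, Fisher's exact test), including IGFBP7, 5.94-fold, and FSTL1, 3.87-fold in the authors' deposited table. PLAU, the urokinase gene, was 5.58-fold lower in the authors' deposited table. With only rows of adjusted p below 0.01, 129 of 141 genes of the authors' deposited table were listed as lower, and none of these 3 groups differed from the rest (adjusted p = 1 each, Fisher's exact test). The EMT factor genes TWIST1, ZEB2 and TCF4 were 6.49-fold, 5.13-fold and 2.53-fold higher in the authors' deposited table (adjusted p = 0.108, Fisher's exact test).

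All 7 squamous and cornified-envelope genes in the authors' deposited CD44/CD24 table were listed as lower (adjusted p = 0.241, Fisher's exact test), among them KLK10, 22.5-fold, and KLK6, 5.88-fold. The luminal keratin gene KRT8 was 6.12-fold lower in the authors' deposited table (adjusted p = 1, Fisher's exact test). Of the stem cell genes, NOTCH3 was 7.40-fold and FZD7 3.09-fold higher and ITGA6 8.93-fold lower in the authors' deposited table (adjusted p = 0.411, Fisher's exact test). The inflammatory genes TNFAIP6 and CXCL1 were listed as higher, CXCL1 by 9.59-fold, and IL1RN was 9.01-fold lower in the authors' deposited table (adjusted p = 0.411, Fisher's exact test). Among RAS-MAPK output genes, the growth factor genes TGFA and HBEGF were 16.2-fold and 12.1-fold lower, UPP1 6.71-fold lower and EREG 2.63-fold higher in the authors' deposited table (adjusted p = 0.83, Fisher's exact test). ST6GALNAC5 was 10.4-fold lower in the authors' deposited table, and ganglioside enzyme genes as a group had an adjusted p of 0.744 by Fisher's exact test. The interferon-stimulated gene BST2 was 8.11-fold higher and the leukocyte marker CORO1A 7.85-fold lower in the authors' deposited table (adjusted p = 0.49 and 1 for their lists, Fisher's exact test). LUM and TWIST1 were the fibroblast markers listed, both as higher (adjusted p = 0.241, Fisher's exact test). Cell cycle, TGF-beta, immediate early, hypoxia, unfolded protein response, cholesterol synthesis and endothelial marker genes had no member in the authors' deposited CD44/CD24 table.

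**Figure D1:**
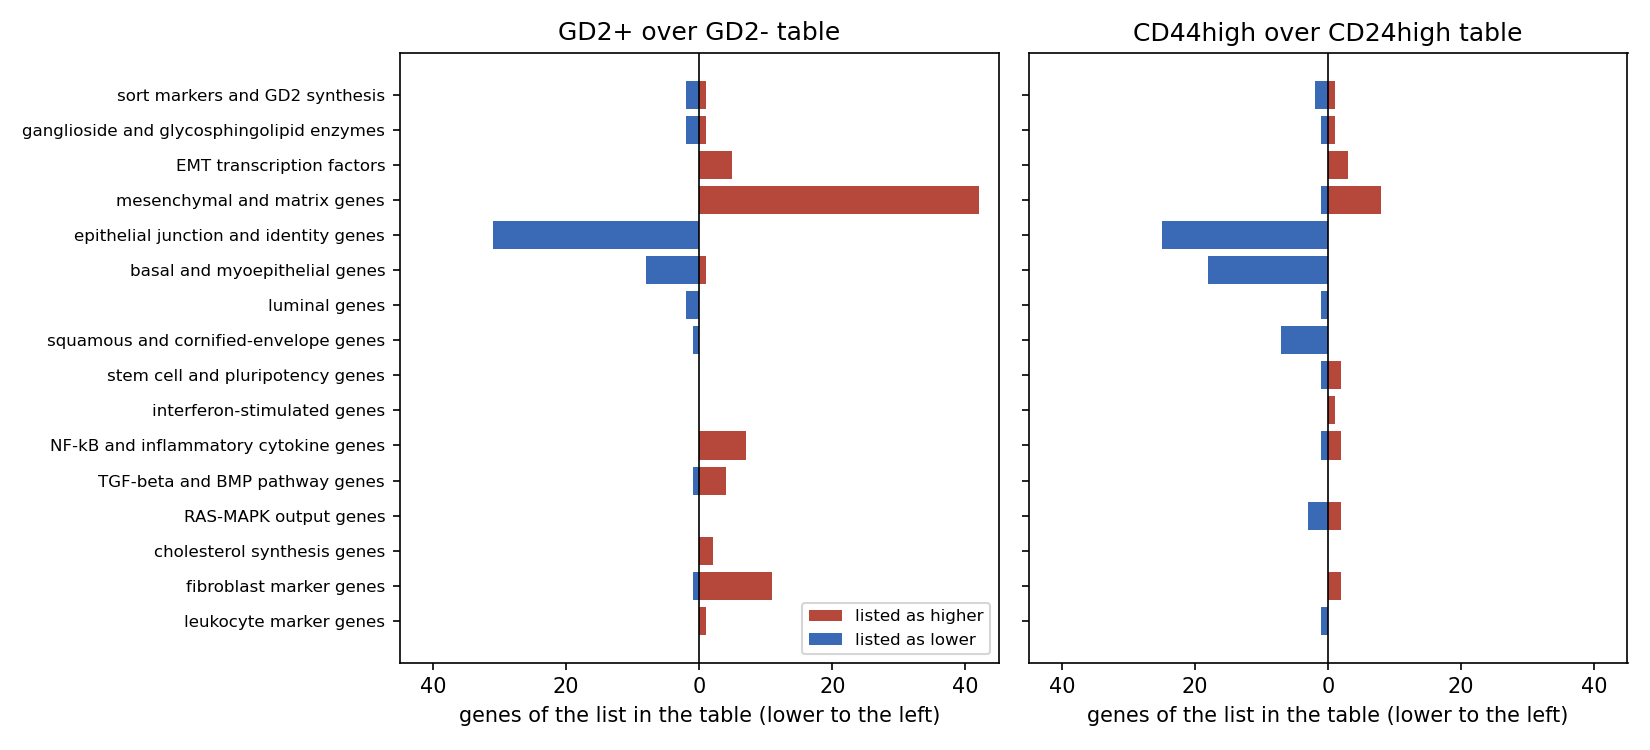
Number of genes of each fixed list in the authors' deposited GD2 table (left) and CD44/CD24 table (right). Bars to the right count genes listed as higher in GD2+ or CD44high cells and bars to the left genes listed as lower; mesenchymal genes reach 42 in the GD2 table and 8 in the CD44/CD24 table.

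The authors' deposited tables shared 149 genes whose rows all pointed the same way within a table. Of these, 115 were listed as lower and 33 as higher in both GD2+ and CD44high cells, 99.3% in the same direction (95% Clopper-Pearson interval 96.3 to 100, two-sided Fisher's exact test p = 2.63e-32). The exception came from matching symbols: the entry MICAL2 was 3.90-fold higher in GD2+ cells and the entry MICALCL, an older symbol of the same gene, 3.37-fold lower in CD44high cells in the authors' deposited tables. With symbols as the authors' deposited tables give them, 148 genes were shared and 100% had the same direction. Log2 fold changes of the shared genes correlated across genes with a Pearson r of 0.889 and a Spearman rho of 0.757. With only rows of adjusted p below 0.01 in both tables, 70 genes were shared, 68 lower and 1 higher in both, r was 0.636 and rho 0.463 (two-sided Fisher's exact test p = 0.0286). The interval and the Fisher's exact tests over shared genes treat genes as independent, which they are not, and measure no spread between arrays or cultures. Among shared genes listed as lower, such as CDH1, EPCAM and KRT6A, 93 of 115 had the larger fold in the authors' deposited CD44/CD24 table. Among those listed as higher, such as TNFAIP6 and TWIST1, 24 of 33 had the larger fold in the authors' deposited GD2 table. This agreement in direction rests on the reading of the GD2 table given above: with its ratio turned, 0.7% had the same direction and r was -0.889, by construction.

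**Figure D2:**
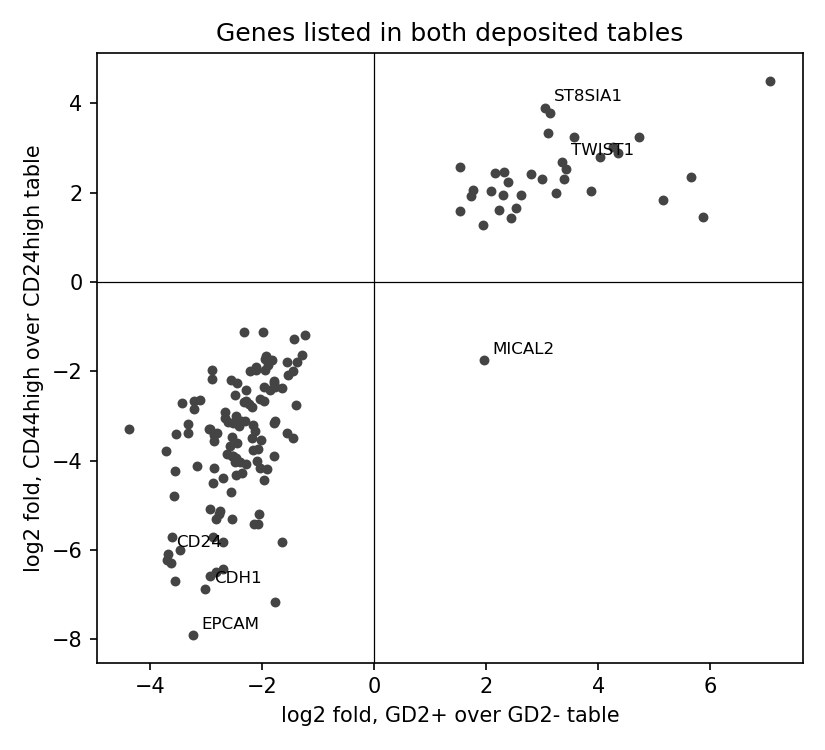
Log2 fold changes of the 149 genes listed in both of the authors' deposited tables, GD2+ over GD2- cells on the horizontal axis and CD44high over CD24high cells on the vertical axis. Each point is a gene, and the only point whose fold changes differ in sign joins the entries MICAL2 and MICALCL, which the reference holds as 1 gene.

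Mesenchymal and matrix genes were found more often in the authors' deposited GD2 table alone (37 genes) than in the CD44/CD24 table alone (4 genes; adjusted p = 1.3e-05 over 15 lists, two-sided Fisher's exact test). Collagen genes such as COL1A1 and COL3A1 and the fibrillin gene FBN1 were among these 37. Basal and myoepithelial genes were spread the other way, 3 against 12 genes, without passing the threshold (adjusted p = 0.0509, Fisher's exact test). Squamous genes, 1 against 7, did not pass either (adjusted p = 0.0745, Fisher's exact test), nor did fibroblast markers, 11 against 1, or RAS-MAPK output genes, 0 against 5 (adjusted p = 0.0638 each, Fisher's exact test). Of the epithelial genes, 22 were in both tables, 9 in the GD2 table alone and 3 in the CD44/CD24 table alone (adjusted p = 0.403, Fisher's exact test). For the other lists with genes in either table, adjusted p was 0.172 or above. These tests also treat genes as independent. The highest listed adjusted p was 0.00107 in the authors' deposited GD2 table and 0.0403 in the CD44/CD24 table, and how rows were chosen is not given in the sources used here, so absence from a table does not show an unchanged gene.

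On the arrays labelled GD2+ and GD2-, 1321 probe sets were higher and 1459 lower in arrays labelled GD2+ (limma, adjusted p below 0.05). The probe set with the largest positive change was higher by 5.81 log2 units (SE 0.29, adjusted p = 6.99e-07), at 10.43 ± 0.51 against 4.62 ± 0.55 (SD, n = 3 each). The next was higher by 5.74 (SE 0.40). The largest negative log2 fold changes were -4.22 (SE 0.74, adjusted p = 0.00705) and -4.05 (SE 0.67, adjusted p = 0.00494). When only these 6 arrays were fitted, 721 probe sets passed, 467 higher and 254 lower, so that most were higher, and the probe sets at -4.22 and -4.05 did not (adjusted p = 0.101 and 0.0939, limma). Leaving out GD2+ replicate 2 or 3 gave 1665 and 1567 probe sets, and leaving out probe sets ending in _x_at or _s_at, so that fewer were tested, 1607. The highest count with a single array left out was 3738.

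On the arrays labelled CD44high and CD24high, 864 probe sets were higher and 837 lower in arrays labelled CD44high (limma). The probe set with the largest positive change was higher by 7.30 log2 units (SE 0.97, adjusted p = 0.00203), at 11.04 ± 0.65 against 3.75 ± 0.09 (SD, n = 3 each), and the next by 7.25 (SE 1.12). The largest negative log2 fold changes were -3.09 (SE 0.64, adjusted p = 0.0248) and -3.03 (SE 0.43, adjusted p = 0.00306). The 6 arrays alone gave 3326 probe sets, 1749 higher and 1577 lower, and the 12 arrays without probe sets ending in _x_at or _s_at gave 1100. Leaving out CD24high replicate 2 or 3 gave 838 and 935, and leaving out CD44high replicate 1, 2 or 3 gave 951, 822 and 868. Without CD24high replicate 1, 2 or 3 or CD44high replicate 1, 2 or 3, the probe set at -3.09 missed the threshold (limma, adjusted p = 0.0735, 0.0714, 0.104, 0.0517, 0.104 and 0.109; 0.00016 to 0.109 over all alternatives).

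The labelled sorts moved in opposite directions on the arrays. Their log2 fold changes correlated across probe sets with a Pearson r of -0.685 and a Spearman rho of -0.447. All 996 probe sets past the threshold in both comparisons had opposite directions, against 43.3 opposite and 43.3 in the same direction for independent lists. The difference between the sorts was past the threshold at 5007 probe sets, 2233 positive and 2774 negative (limma). The largest differences were 8.26 (SE 0.40) and 7.90 log2 units (SE 0.57), and -11.35 (SE 1.38) and -10.65 (SE 1.38). With the sign of the GD2 contrast turned, the count was 87 and r was 0.685. In the labels, the short description codes of the GD2 arrays could also be read as the reverse of their titles, so the direction of this contrast is not settled.

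**Figure D3:**
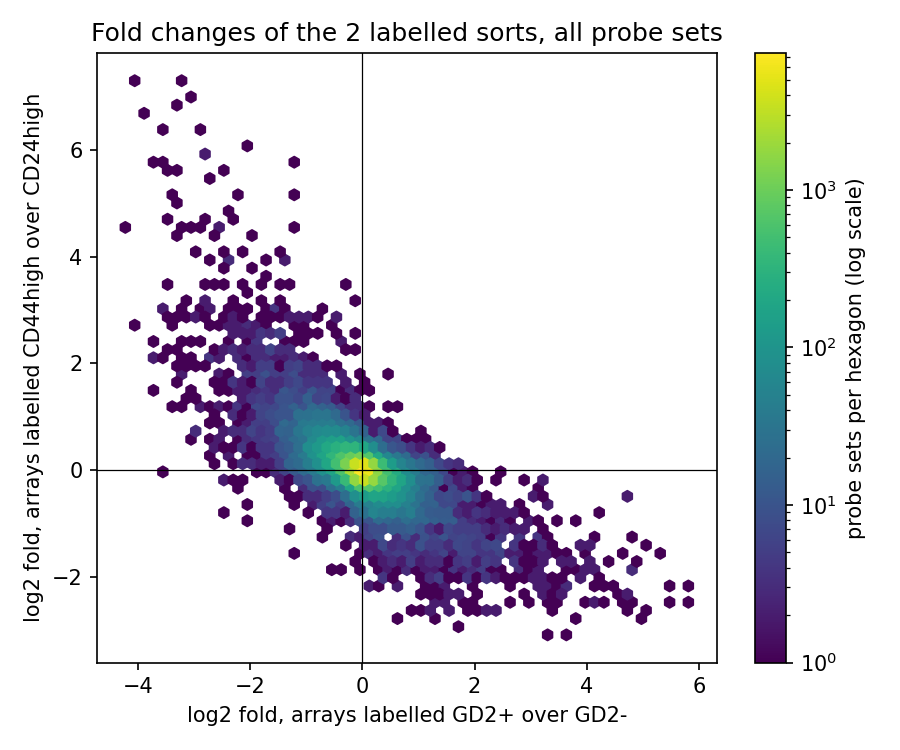
Log2 fold changes of 54613 probe sets, arrays labelled GD2+ over GD2- on the horizontal axis and arrays labelled CD44high over CD24high on the vertical axis. Colour gives the number of probe sets per hexagon on a log scale, and the cloud runs from upper left to lower right (r = -0.685).

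Between the sorts, 7256 probe sets were higher and 8258 lower in arrays labelled GD2+ than in arrays labelled CD44high (limma). The largest changes were 6.15 (SE 0.24) and 5.98 log2 units (SE 0.28), and -4.60 (SE 0.82) and -4.35 (SE 0.76). The balance turned round at a fold of at least 2, with 3439 higher and 1782 lower, while leaving out probe sets ending in _x_at or _s_at gave 3367 higher and 5990 lower. In arrays labelled GD2- against CD24high, 9565 probe sets were higher and 10901 lower (limma). Here the largest changes were 8.55 (SE 0.70) and 7.88 log2 units (SE 0.88), and -8.19 (SE 0.76) and -6.97 (SE 0.40). At a fold of at least 2 there were 4847 higher and 2835 lower, and without probe sets ending in _x_at or _s_at 5052 higher and 7780 lower. Control probe sets separated the same sets of arrays. The 8 control probe sets for RNA added before labelling averaged 8.766 ± 0.127 in the arrays labelled CD44high or CD24high and 4.156 ± 0.082 in those labelled GD2+ or GD2- (SD, n = 6 each, exact permutation test, two-sided p = 0.00216, the smallest that 924 splits allow). The beta-actin control was brighter at its 3' than its 5' probe set by 3.842 ± 0.564 log2 units in the CD44/CD24 arrays and by 0.192 ± 0.077 in the GD2 arrays (SD, n = 6 each, exact permutation p = 0.00216). For the GAPDH control this difference was 1.477 ± 0.253 log2 units in the CD44/CD24 arrays and 0.008 ± 0.057 in the GD2 arrays (SD). Sort, labelling and RNA quality could not be separated in these comparisons.

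**Figure D4:**
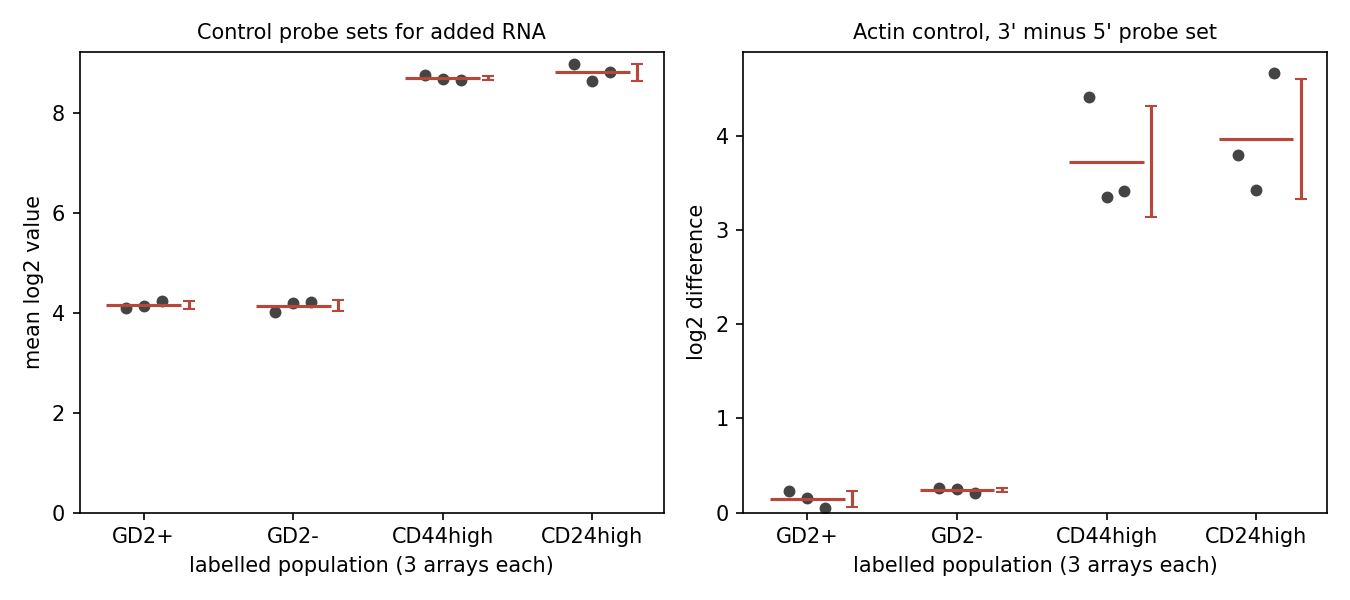
Mean log2 value of control probe sets for added RNA (left) and log2 difference between the 3' and 5' beta-actin control probe sets (right), per array by labelled population. Points are arrays, horizontal lines are means and bars are SD over 3 arrays; the CD44high and CD24high arrays lie above the GD2+ and GD2- arrays in both panels.

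Counts at the limits of the authors' deposited tables depended on the fit. In fits of the 6 arrays of a sort, at the highest adjusted p and the smallest fold of the authors' deposited GD2 table, the arrays labelled GD2+ and GD2- gave 31 probe sets, all higher in GD2+ arrays, beside the 322 higher and 278 lower rows of the authors' deposited table. The arrays labelled CD44high and CD24high gave 326 higher and 261 lower probe sets in CD44high arrays at these limits. At the limits of the authors' deposited CD44/CD24 table, which held 167 higher and 411 lower rows, the arrays labelled GD2+ and GD2- gave 358 higher and 139 lower probe sets. The arrays labelled CD44high and CD24high gave 730 higher and 562 lower probe sets there. In the fit of all 12 arrays, the limits of the GD2 table gave 293 higher and 56 lower probe sets on the GD2 arrays and 71 higher and 93 lower on the CD44/CD24 arrays (limma). The limits of the CD44/CD24 table gave 634 higher and 604 lower on the GD2 arrays and 458 higher and 397 lower on the CD44/CD24 arrays in that fit. These counts also moved with single arrays: at the limits of the GD2 table, the GD2 arrays went from 349 to 219 and 203 without GD2+ replicate 2 or 3, and the CD44/CD24 arrays from 164 to 97, 9 and 32 without CD24high replicate 1, 2 or 3 and to 30, 21 and 19 without CD44high replicate 1, 2 or 3. At the limits of the CD44/CD24 table, the CD44/CD24 arrays went from 855 to 516 and 563 without CD24high replicate 2 or 3 and to 505 and 562 without CD44high replicate 2 or 3. In the 6-array fits, with any of the 6 arrays labelled GD2+ or GD2- left out, 0 probe sets reached the limits of the GD2 table (limma), while 1022 to 1565 had its smallest fold and an unadjusted p below 0.05. At these limits the CD44/CD24 arrays gave 276 without CD24high replicate 2, and 217 and 213 without CD44high replicate 2 or 3. At the limits of the CD44/CD24 table the GD2 arrays gave 145 and 127 without GD2+ replicate 2 or 3, and 311 without GD2- replicate 1. These counts do not say whether the same genes were behind them.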

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

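Tests that set the deposited tables or their limits against the arrays, a divergent array and the 12-array fit included, the test of control probe sets and the correlation of cross-sort contrasts were chosen after the results had been seen. Those of normalization and noise behind the opposite directions and of other splits were not. The difference between the labelled sorts was past the threshold at 5007 probe sets, which drew attention because it tests the sorts' effects against each other. Of 100 splits drawn within both sorts, the real one included, 1 gave as many at the adjusted threshold (the highest other gave 460). The other splits mix labelled populations within a group, which widens the spread they are tested against. Chance is therefore made less likely by these splits but not excluded. For comparisons of 3 against 3 arrays there are only 10 splits, too few for a share under 0.05. The real split was the 1 with the highest count each time. For GD2+ against GD2- it gave 2780 and the highest other 1199, for CD44high against CD24high 1701 and 0, for GD2+ against CD44high 15514 and 0, and for GD2- against CD24high 20466 and 0 (limma). At an unadjusted p below 0.05, the real and the highest other count were 11366 and 9025 for the difference, 9728 and 8848 for GD2+ against GD2-, 6746 and 2578 for CD44high against CD24high, 21579 and 2956 for GD2+ against CD44high, and 25648 and 4056 for GD2- against CD24high.

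The opposite directions of the labelled sorts were weighed first. Quantile normalization of the deposited values and a filter on dim probe sets left r at or below -0.685. This argues against dim probe sets and remaining differences in distribution between arrays as the source. Median centring shifts all fold changes of a comparison alike, so it could not change r and does not test this. The authors' own normalization could not be varied here. Noise of weakly changed probe sets would give mixed directions, but 100% of the probe sets past the threshold in both comparisons were opposite. This covers those 996 probe sets and not the more weakly changed ones, which also enter r. Of the genes shared by the deposited tables, 0.7% were opposite, a single gene listed as MICAL2 and MICALCL, and r was 0.889, which would speak against sorts that select opposite cell states and for labels of 1 sort turned round. Both readings rest on the unstated numerator of the GD2 table (turned, 99.3% were opposite and r was -0.889), so opposite states and turned labels cannot be told apart here.

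The resemblance of the deposited tables to the arrays labelled with the other sort depended on the fit. In 6-array fits the other sort gave 0.98 and 0.86 times the rows at the limits of the GD2 and the CD44/CD24 table (0.36 and 0.22 at the lowest with 1 array left out), but in the 12-array fit 0.27 and 2.14 times (0.01 to 0.16 and 1.69 to 2.96 with 1 left out), against 0.58 and 1.48 on each table's own arrays (0.34 to 0.59 and 0.87 to 1.46). Array columns exchanged between the sorts are therefore open, as the ratios move with single arrays and the fit behind the tables is not known. With 1 array left out, the GD2 arrays gave 0 probe sets at the limits of the GD2 table in 6-array fits (1022 to 1565 at an unadjusted p below 0.05, limma) and at most 354 in 12-array fits; a divergent array stays open, because leaving 1 out lowered the count on the CD44/CD24 arrays as well, from 587 to between 213 and 520. Processing choices took the GD2 arrays from 31 to at most 349 probe sets, with all 12 arrays in the fit, and the authors' own method is not known, so processing, a divergent array and exchanged columns cannot be told apart.

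Control probe sets, which no comparison of populations used, differed between the sets of 6 arrays by 4.61 log2 units for added RNA. Between the sets 15514 and 20466 probe sets also differed, for GD2+ against CD44high and GD2- against CD24high. The 4.61 lies far beyond the range within each set, as a labelling or amplification difference could give. However, these controls averaged 4.156 in the GD2 arrays, below the mean array median of 5.443 there. Added RNA that was absent from that set would also give this, so the 4.61 does not show an effect on other probe sets. The pairs of cross-sort contrasts that share no array correlated with r = 0.509 (GD2+ minus CD44high with GD2- minus CD24high) and r = 0.877 (GD2+ minus CD24high with GD2- minus CD44high), so part of the difference was common to all arrays of a sort. Sorted populations, labelling and RNA quality cannot be told apart for that part, because every array of a sort was on the same side.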

How the results depend on the processing

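Alternatives on the deposited tables and at their limits were chosen after seeing the data. Planned choices by gene, camera and fry tests and the share of table entries past the threshold were not run, for want of a link between probe sets and genes, and a pseudocount does not apply to log2 values. In the order GD2+ against GD2-, CD44high against CD24high, difference, GD2+ against CD44high and GD2- against CD24high, leaving out _x_at and _s_at probe sets gave 1607, 1100, 3002, 9357 and 12832 probe sets, with fewer probe sets tested. A fold of at least 2 gave 1325, 912, 5221 and 7682, the difference staying within 1.5 times. Only the 6 arrays gave 721 and 3326 within the sorts, so which sort had more probe sets past the threshold depended on the fit. The 12-array fit pools 1 spread per probe set over both sorts. Differences between replicate arrays had an SD of 0.199 to 0.547 in the GD2 sort and 0.223 to 0.332 in the CD44/CD24 sort. Whether this moved the counts was not tested. Leaving out 1 array gave 1567 to 3738, 822 to 2439, 3723 to 5672, 11771 to 17497 and 17255 to 20808, and r from -0.708 to -0.59. Turning the sign of the GD2 contrast gave r = 0.685 by construction. The difference, tested again with that sign, was past the threshold at 87 probe sets, a count that turning the sign does not fix. With a replicate block the counts were 4328 and 2601 within the sorts, and within 1.5 times elsewhere. Same-numbered arrays did not all deviate together within the sorts (r = 0.47, 0.39 and 0.03 for GD2, 0.09, 0.35 and 0.08 for CD44/CD24) or between GD2+ and CD44high (0.21, 0.19 and -0.01), so the numbers were not taken to pair these arrays. Over all 12 pairs, GD2- with CD24high included, 9 correlated best with their own number, a hint from the data that leaves some pairing open. Quantile normalization, median centring, the dim filter and the robust variance kept every count within 1.5 times. Of 365 values of the 20 named probe sets, 357 stayed past the threshold and 8 did not, with none reversed. The same-direction share was 100% with at least 4-fold in both tables, where fewer genes were tested, and 100% with symbols as the files give them, where MICAL2 and MICALCL are not joined; turning the ratio of the GD2 table gave 0.7% by construction. It was 98.7% with genes in both directions kept and 98.6% at adjusted p below 0.01 in both tables, where 70 genes with 1 higher in both were left and r was 0.636. Mesenchymal genes in the CD44/CD24 table reversed at adjusted p below 0.01, where PLAU alone was left (higher minus lower -1); 6 other list calls were lost, for which fewer genes were tested. At the limits of the GD2 table, the suffix filter gave 14 probe sets on GD2 arrays and 392 on CD44/CD24 arrays, all 12 arrays in the fit gave 349 and 164, and leaving out 1 array gave 0 to 0 and 213 to 520. At those of the CD44/CD24 table these were 306 and 852, 1238 and 855, and 127 to 504 and 1141 to 1486; the cause of the change with 12 arrays was not tested. Signal over background was not given, so dim probe sets are open.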

Other observations

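Some genes outside the fixed lists were picked after their values were seen. Members of the fibroblast growth factor receptor family were listed on different sides. FGFR1 was 8.77-fold higher and FGFR2 9.32-fold lower in GD2+ cells in the authors' deposited table. FGFR2 was 6.32-fold and FGFR3 21.96-fold lower in CD44high cells in the authors' deposited table. The collagen receptor gene DDR2 was higher in both, by 8.65-fold in GD2+ and 10.2-fold in CD44high cells in the authors' deposited tables. Hyaluronan synthase genes, whose product binds CD44, appeared once per table: HAS2 was 154-fold higher in GD2+ cells and HAS3 9.60-fold lower in CD44high cells in the authors' deposited tables. The connexin gene GJB6 was 4.41-fold and 42.55-fold lower in GD2+ and CD44high cells in the authors' deposited tables, and the connexin gene GJB5 was 14.6-fold lower in CD44high cells in the authors' deposited table. No test was run on these genes.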
